A study of Mus musculus with 8 samples.

How the data were processed

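The deposited values covered 8 Clariom S Mouse arrays of dorsal skin RNA from male C3H mice, in 4 groups of 2 that were set by the labels: Milli-Q water, minoxidil, tieghemelin and maslinic acid. Per the labels, mice were 7 weeks old, were kept for 7 days before use, were assigned at random to groups of 8, were depilated and were then treated each day for 20 days, and 9.4 µg of total RNA was taken for the arrays. Per the series' design text, the scans were normalised in Transcriptome Analysis Console, and per the submitters' processing notes Affymetrix Expression Console and RMA were also used. The deposited values were taken as log2 from their range, since a ceiling of 19.93 was shared on 6 of 8 arrays, which limits differences between the brightest probe sets. RMA corrects background, quantile-normalises probes across arrays and summarises them per probe set, so differences in total signal between arrays are largely removed from such values. Per the series' design text, the study took genes at a fold change of at least 1.7 and an unadjusted p of at most 0.05, and the test behind that p and a genome build were not given in the sources used here. Control array 1 kept a narrower spread of log2 values (SD 1.32) than the others.

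Control probe sets (6640) were left out, and the other 22206 were tested without further scaling or filtering. Gene names came from the platform annotation through probe set identifiers, and all 19572 probe sets with 1 symbol matched a RefSeq gene by gene ID, 0 had several and 2634 were unnamed. After the data were seen, each named gene was set against the median of the antigenomic background probe sets of each array. Of 214 named values, 57 had a group with no array above it, 8 of them both groups. Such a gene is given as a bound, with each array of the dim group at the higher of its value and that median, or without a fold, and list medians and tests use the measured values. The median is no detection call for a single probe set. Groups were compared with limma 3.58.1 in R 4.3.3 by a linear model on all 8 arrays, which left 4 residual degrees of freedom, with moderated standard errors from eBayes and Benjamini-Hochberg adjustment over all probe sets of a comparison. The 6 comparisons were each treatment against control and each pair of treatments. With 2 arrays against 2, the smallest 2-sided permutation p is 0.33, so limma's model across all genes was used. Before the data were examined, the design, the alternatives, the gene lists and the rule for named genes were fixed.

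By that rule, each comparison names the 10 genes with the largest log2 difference per direction among probe sets with 1 symbol, an adjusted p under 0.05 and no overlap between the arrays of the groups, skipping predicted genes. No probe set qualified, so all places were filled, as the rule sets out, with probe sets at the study's thresholds whose arrays did not overlap. The rule also allows up to 4 members of each list with the largest absolute difference, and any hair cycle growth factor or minoxidil target. The text gives the first 5 per direction for the comparisons with minoxidil, and its list members were taken by size alone.

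There were 37 lists, 19 of processes and 18 of cell types, which held 710 genes. Lists with at least 5 measured members (36) were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation, under which 0 lists were called in any of the 4 comparisons tested as planned. The counts of members adjusted over the list alone used the unadjusted p of the same model. Shared controls were handled with 100 simulated draws of unchanged groups.

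The alternatives were a replicate block, a filter that kept probe sets above the median mean log2 value, quantile normalization, a shift of each array to a common median, eBayes with trend and robust settings, no moderation, array weights, a fit on the 2 groups compared alone, an estimated correlation, camera on ranks, and leaving out each array in turn. An array left out leaves its group with 1 array, which is then assumed to vary like those of the other groups. A crossed block, the estimated correlation without control array 1, and lists against minoxidil were added after seeing the data. The code was tested on simulated data built from these arrays with 50 changed genes per size. All arrays of a probe set were drawn with 1 common spread, whereas the real control arrays differed far more than the others. The shares called there therefore do not carry over to these data. With tieghemelin, Tnnt3 differed from control by -8.26 and had a limma adjusted p of 0.364 with all 8 arrays. For minoxidil against control with all 8 arrays, 0% of changes of 1 log2 unit, 28% of 2 and 96% of 4 were called, with 9 false calls. Without control array 1 these shares were 8%, 70% and 100%, with 5 false calls.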

Results

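Gene expression was measured in dorsal skin of male C3H mice, an inbred strain, after 20 days of daily topical treatment that followed depilation. Total RNA was hybridised to Clariom S Mouse microarrays, which carry probe sets for well-annotated genes, and the deposited values were on a log2 scale. There were 4 groups with 2 arrays each: Milli-Q water as control, minoxidil, the compound tieghemelin, and maslinic acid, a pentacyclic triterpene acid. The titles of both control arrays call them the control of tieghemelin and maslinic acid. No other control was given for minoxidil, so it was compared with the same arrays. Each compound was applied at 1%, although minoxidil array 2 was called 1% in its description and 2% in its source name. The study was designed to examine hair growth under tieghemelin and maslinic acid, with minoxidil, a known hair growth drug, as a further treatment. In all, 22206 probe sets entered the tests, of which 19572 carried 1 gene symbol and 2634 carried none. The number of arrays limited the precision. The labels do not tie arrays to single mice, so p-values measure the spread between these arrays, which may be technical.

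Control array 1 stood apart from the other 7 arrays. Its log2 values correlated with theirs at a Pearson r of 0.518 to 0.538 across probe sets, whereas the other 7 correlated with one another at 0.901 to 0.966. The bacterial hybridization control bioB read 4.48 on control array 1 and at least 8.29 elsewhere, and cre read 6.25 against at least 12.45. Genes for ribosomal proteins, abundant in every tissue, ranked at a median percentile of 67.6 on that array and 88.6 to 94.9 on the others. Odorant, vomeronasal and trace-amine receptor genes, which act in sensory neurons of the nose, ranked at a median percentile of 48.4 there and 65.6 to 72.7 on the other arrays. On each array a positive control probe set exceeded a negative one with a probability of 0.454 to 0.501, where 0.5 is no separation. Antigenomic probe sets, which match no mouse sequence and measure background, had medians of 7.75 and 7.61 on the control arrays and 7.51 and 7.33 with minoxidil. They were 7.02 and 6.97 with tieghemelin and 6.96 and 7.08 with maslinic acid, so calls above background rest on medians that differ between groups. A gene above its array's background median on no array of a group is given as at least so many fold higher or lower, with the dim group set to background. It has no fold where that left no difference or neither group was above background. Each comparison with control is given with all 8 arrays, as planned, and without control array 1.

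**Figure D1:**
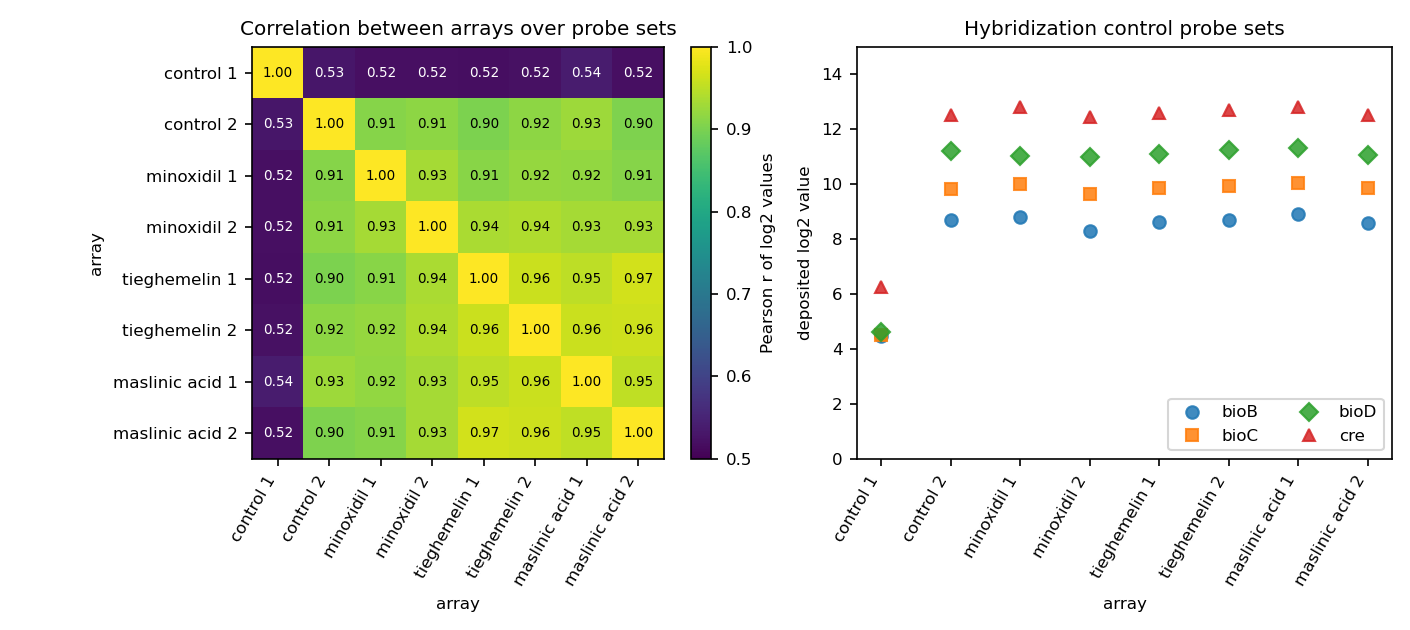
Pearson correlation of log2 values between every pair of arrays (left) and the deposited log2 values of 4 bacterial hybridization control probe sets on each array (right, 1 point per probe set and array). Control array 1 correlated with the rest at no more than 0.538, and bioB read 4.48 on it.

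With minoxidil, the named genes with the lowest values relative to control were mostly those of skeletal muscle. Tnnt3, which encodes fast skeletal troponin T, read 10.97 ± 0.24 (SD, n = 2) with minoxidil and 16.06 ± 0.27 in control skin, 34.2-fold lower (log2 -5.10, SE 1.15). The myosin heavy chain genes Myh4, Myh8 and Myh1 differed by -4.79, -4.52 and -3.08, the tropomyosin gene Tpm2 by -3.61, and Neb, for the thin filament protein nebulin, by -2.94. Fhl1, a LIM-domain protein of striated muscle, differed by -4.80 and the glycolytic enzyme gene Aldoa by -3.14, while Usp9x, a deubiquitinase gene, was at least 3.98-fold lower. Rbm47, an RNA-binding protein gene, was above background on control array 1 alone among the 4 arrays compared, and has no fold. Fhl1, Aldoa and Neb differed by -6.22, -4.72 and -4.53 without control array 1, and Rbm47, then below background throughout, by -0.64. Of 31 measured skeletal muscle markers, 27 were lower and 12 of them met the study's thresholds, with a median of -1.31 (2.47-fold). Limma's camera test gave that list an adjusted p = 1.91e-08, and an adjusted p = 0.643 with an estimated correlation. No muscle marker passed when adjusted over all genes, and 4 passed when adjusted over the list alone. The median was -2.74 without control array 1, -0.70 without control array 2, where the call ended (adjusted p = 0.315, with a range of 1.32e-22 to 0.693 over the alternatives), -1.98 without minoxidil array 1, and -2.25 after quantile normalization.

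Apart from Olfr206, the named genes with the highest values under minoxidil had smaller folds without control array 1. Mup19, a major urinary protein gene, was 17.7-fold higher with all arrays and 1.53-fold higher without control array 1, and the zinc finger genes Zfp971, Zfp979 and Zfp965 went from 13.6-, 12.3- and 7.30-fold to 1.52-, 1.89- and 1.95-fold. The pancreatic amylase gene Amy2a4 and Btbd35f20 went from 10.2- and 7.27-fold to 1.92- and 1.49-fold, and the receptor genes Olfr994, Olfr1537 and Vmn2r84 from 11.7-, 7.39- and 7.28-fold to 5.26-, 3.71- and 2.92-fold. Olfr206, an odorant receptor gene, lay below background on both control arrays and was at least 2.49-fold higher, with a limma adjusted p of 0.075 without control array 1 (0.000562 to 0.91 over the alternatives). Olfr994, Amy2a4, Olfr1537 and Vmn2r84 were above background on 1 of the 2 control arrays, array 2. With all 8 arrays, 18.7% of the 1429 receptor probe sets met the study's thresholds, against 10.8% of others. Of these receptors 253 were higher and 14 lower, so the named ones do not stand alone. As a class, receptors ranked lowest on control array 1, which enters that share. Without that array the share of receptors was nearer to that of others but stayed above it.

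Among hair genes, keratin-associated proteins, which cross-link hair keratins, were higher with minoxidil for 39 of 50 members, with a median of 0.96 (camera adjusted p = 0.00246, and adjusted p = 0.643 with an estimated correlation). Krtap4-1, Krtap5-1 and Krtap4-2 differed by 2.11, 2.05 and 1.97 (0.92, 0.25 and 0.48 without control array 1), and 0 members passed when adjusted over the list alone. That call ended without control array 1, where the median was 0.01 (adjusted p = 0.888, with 2.31e-05 to 0.923 over the alternatives), and without control array 2 the median was 1.59. In the inner root sheath, the layer that moulds the growing shaft, Krt27, Krt71 and Tchh differed by -2.13, -1.73 and -1.23 (-0.84, -4.20 and -1.24 without control array 1) and Krt28 was at least 3.62-fold lower, and Krt28 was the 1 member of 11 that passed when adjusted over the list alone. The inner root sheath list was not called with all arrays (median -0.40, adjusted p = 0.11), was called without control array 1 (-0.84, adjusted p = 1e-04) and among brighter probe sets (adjusted p = 0.0107, with 1e-04 to 0.84 over the alternatives), and turned to 0.17 without control array 2, where Krt71 turned to 0.74. With an estimated correlation it was not called, with an adjusted p = 0.643 for all arrays and 0.693 without control array 1. Among 12 hair shaft keratins only Krt39 passed when adjusted over the list alone, at 1.66 (SE 0.38), above background on 1 of the 2 control arrays.

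Interferon-stimulated genes were lower for 21 of 25 members under minoxidil, with a median of -0.59 (camera adjusted p = 0.013, and adjusted p = 0.643 with an estimated correlation). The RNA sensor gene Ddx58 and Cmpk2 were at least 1.24- and 1.23-fold lower, but above background on control array 1 alone, the transcription factor gene Irf7 lay below background in both groups, and 0 passed when adjusted over the list alone. The call ended without control array 1 (median -0.03, adjusted p = 0.926), without minoxidil array 1 (-0.48, adjusted p = 0.0752) and among brighter probe sets (adjusted p = 0.055, with 0.00222 to 0.94 over the alternatives), and the median was -1.04 without control array 2. Of 17 pigment production genes 15 were higher without a list call (adjusted p = 0.073), and 3 passed when adjusted over the list alone: Mitf, a master transcription factor of pigment cells, at least 1.87-fold higher, Pmel, a melanosome matrix protein gene, at 1.69 (1.08 without control array 1), and Oca2, a melanosome transporter gene, at least 1.82-fold higher. Without control array 1, 11 of the 17 were higher, the median was 0.23 where it had been 0.60, and 1 passed. Krtap4-1, Pmel, Ptgs2, Dpt and Dcn were above background on 1 of the 2 control arrays, and Dpt on 1 of the 2 minoxidil arrays. Dermal fibroblast markers were lower for 8 of 11 members (median -0.56, adjusted p = 0.317), among them Mfap5, an elastic fibre gene, at least 1.83-fold lower but above background on control array 1 alone (a difference of 0.02 without it), Dpt at -1.11 (-1.79 without control array 1), Lum at -1.08 and Dcn at -1.05 (-2.74 without control array 1 and 0.65 without control array 2). That list was called without control array 1 (-0.56, adjusted p = 0.000925, with 0.000925 to 0.937 over the alternatives), though not with an estimated correlation there (adjusted p = 0.693 with an estimated correlation), and its median turned to 0.43 without control array 2. In the hair cycle growth factor list 0 of 31 members passed, with Bmp6 at -1.32 (-0.83 without control array 1), and Egf and Grem1 were above background on control array 1 and on no other array compared. None of the 6 measured genes of minoxidil targets and activation met the study's thresholds, and Kcnj8, a subunit of the potassium channel that minoxidil opens, and the prostaglandin synthase gene Ptgs2 differed by 0.56 each (0.02 and 0.32 without control array 1).

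Limma called 0 probe sets at an adjusted p under 0.05 for minoxidil with all 8 arrays (smallest adjusted p 0.44), an ordinary linear model without moderation also called 0, and 2502 had an unadjusted p of at most 0.05, where 1110 would by chance alone. All 2502 also met the study's 1.7-fold threshold, 1549 higher and 953 lower. The mean was 3207 in simulated unchanged groups, whose control spread was modelled and is only a rough match to these arrays. Leaving out control array 1 gave 2867 such probe sets (1451 higher, 1416 lower), 1192 of them shared with the first count, and Fhl1, named after its value was seen, was the 1 adjusted call (log2 -6.22, adjusted p = 0.0418, with 0.00306 to 0.91 over the alternatives). Without control array 2 the adjusted count was 8363 and the count at the study's thresholds 10508. That count was 1189 and 1320 without minoxidil array 1 or 2, 1572 without either tieghemelin array and 1648 without either maslinic acid array. Arrays of the groups did not overlap for 36.2% of probe sets, where chance gives 33.3% if all arrays compared vary alike. The control arrays differed far more than the treated ones, which raises the share that chance gives, so no excess is shown.

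**Figure D2:**
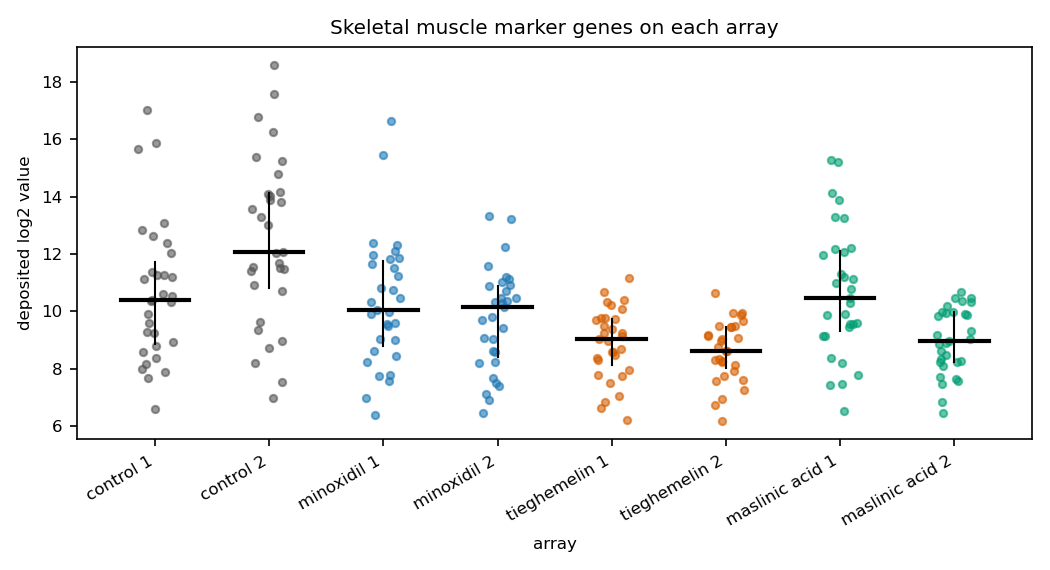
Deposited log2 values of the 31 skeletal muscle markers on each array (1 point per gene), with the median as a thick bar and the quartiles as a thin line. The medians were 10.40 and 12.06 on the control arrays, 10.06 and 10.17 with minoxidil, 9.03 and 8.62 with tieghemelin, and 10.46 and 8.97 with maslinic acid.

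Skeletal muscle genes were again the named genes with the lowest values under tieghemelin. Tnnt3 read 7.81 ± 1.23 (SD, n = 2) with tieghemelin and 16.06 ± 0.27 in control skin, a log2 difference of -8.26 (SE 1.15), although tieghemelin array 2, at 6.94, lay below its background median of 6.97. Myh4, Myh8 and Myh1 differed by -7.70, -6.97 and -5.02, the myosin light chain gene Mylpf by -7.29 and Atp2a1, the calcium pump of fast muscle, by -4.56, and Neb was at least 31.8-fold lower. Fhl1, Aldoa and Car3, a carbonic anhydrase gene of muscle and fat, differed by -5.92, -4.58 and -4.85. These values were -7.35, -6.16 and -7.47 without control array 1, where Mylpf and Atp2a1 differed by -8.24 and -5.25 and Neb was at least 95.9-fold lower. Of the 31 muscle markers 29 were lower, 18 of them at the study's thresholds, with a median of -2.09 (camera adjusted p = 6.44e-17, and adjusted p = 0.79 with an estimated correlation). Adjusted over the list alone 15 markers passed, and none did when adjusted over all genes. The list stayed called without either control array, with a median of -3.50 without control array 1 and -1.36 without control array 2 (adjusted p = 0.000479, with 5.94e-32 to 0.863 over the alternatives).

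The named genes that were highest under tieghemelin included receptor and defensin genes. With all 8 arrays, 15.3% of the 1429 receptor probe sets met the study's thresholds, 192 higher and 26 lower, against 11.5% of others. Control array 1, where receptors ranked lowest, enters that share, and without it the share of receptors no longer exceeded that of others. No list of defensins was tested. Olfr994 was 11.2-fold higher (log2 3.49, SE 0.89) and 5.05-fold higher without control array 1, Vmn2r84 8.11- and 3.25-fold, and the defensin genes Defa25 and Defa40, known from Paneth cells of the gut, 7.58-fold (2.73-fold without it) and at least 3.13-fold. Spink14, a protease inhibitor gene, went from 7.69- to 4.03-fold, Slxl1 from 8.70- to 2.60-fold, Btbd35f13 from 8.13- to 1.49-fold, Amy2a4 from 9.08- to 1.70-fold, Zfp966 from 10.6- to 1.73-fold and Zfp970 from 10.3- to 2.5-fold. Olfr994, Amy2a4, Vmn2r84, Spink14 and Defa25 were above background on 1 of the 2 control arrays.

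Of 50 keratin-associated proteins 40 were higher with tieghemelin (median 0.71, camera adjusted p = 0.00859, and adjusted p = 0.79 with an estimated correlation). Krtap6-1 and Krtap5-1 differed by 2.21 and 2.16 (0.47 and 0.36 without control array 1), whereas Krtap7-1 was at least 3.17-fold lower and was the 1 member that passed when adjusted over the list alone. The call ended without control array 1 (median 0.005, adjusted p = 0.932) and without tieghemelin array 1 (0.75, adjusted p = 0.0516, with 4.95e-05 to 0.932 over the alternatives), and the median was 1.36 without control array 2 and 1.17 among brighter probe sets. Hair shaft keratins were not called (adjusted p = 0.882; median -0.04, but mean 0.10 and a test direction of higher), with Krt39 at 1.37 and Krt40 at 0.99, nor was the inner root sheath (adjusted p = 0.7), with Krt71 at -1.80 (-4.27 without control array 1 and 0.67 without control array 2) and Krt28 at -1.04. Interferon-stimulated genes were lower for 19 of 25 members without a call (adjusted p = 0.0569), Ddx58 at least 1.67-fold lower but above background on control array 1 alone, and Irf7 below background in both groups. Dermal fibroblast markers, with Mfap5 at least 2.46-fold lower but above background on control array 1 alone and Col3a1, a fibrillar collagen gene, at -1.20 (-2.61 without control array 1 and 0.20 without control array 2), were lower for 8 of 11 members (median -0.36, adjusted p = 0.545). They were called without control array 1 (-0.65, adjusted p = 0.0255, with 0.0255 to 0.91 over the alternatives), though not with an estimated correlation there (adjusted p = 0.863 with an estimated correlation), and their median turned to 0.20 without control array 2. In the keratinocyte stress list, Serpinb3a and the alarmin gene S100a9 differed by 2.02 and 1.63 (0.74 and at least 3.74-fold without control array 1) and S100a8 was at least 2.07-fold higher, with 0 of 30 members passing when adjusted over the list alone. Among growth factors 0 of 31 passed, with Bmp6 at -1.64, Fgf22 at 1.63 and Ccn2 at 1.54 (0.45 and 0.82 for the last pair without control array 1). Krt39, Col3a1, Serpinb3a, S100a9, Fgf22, Ccn2 and Ptgs2 were above background on 1 of the 2 control arrays. None of the 6 minoxidil target genes met the study's thresholds, Ptgs2 at 0.56 and Kcnj8 at 0.49 (0.33 and -0.05 without control array 1).

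For tieghemelin, limma called 0 probe sets at an adjusted p under 0.05 with all 8 arrays (smallest adjusted p 0.364), as did the ordinary linear model, and 2609 met the study's thresholds (1558 higher, 1051 lower). Those 2609 were also the probe sets with an unadjusted p of at most 0.05, and simulated unchanged groups gave a mean of 3206. Without control array 1 the adjusted count was 79, 15 higher and 64 lower, and 16 of its 67 named genes were muscle markers. The 67 genes, of which those given here were chosen after their values were seen, included Tnnt3 at -8.44 (adjusted p = 0.0274, with 0.000808 to 0.861 over the alternatives), Tpm1, a tropomyosin gene, at -7.73, Car3 at -7.47, Fhl1 at -7.35 and the keratin genes Krt71 at -4.27 and Krt5 at -4.20. Without either maslinic acid array limma called 3 probe sets, those of Tnnt3, Myh4 and Myh8, and without control array 2 it called 8427. At the study's thresholds the count was 10549 without control array 2 and 815 and 999 without tieghemelin array 1 or 2. It was 3053 (1473 higher, 1580 lower) without control array 1, with 1318 shared. Non-overlapping arrays were found for 40.7% of probe sets against 33.3% by chance for arrays that vary alike. The wider spread of the control arrays raises that chance share, so no excess is shown.

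With maslinic acid, skeletal muscle genes were also among the named lower genes, with a wide gap between its 2 arrays. Myh4 read 11.60 ± 3.60 (SD, n = 2) against 16.90 ± 0.18 in control skin, 39.4-fold lower (log2 -5.30, SE 1.31), and Mylpf, Myh8, Tnnt3 and Neb differed by -4.80, -4.50, -4.21 and -3.30. Fhl1, Aldoa and Tpm2 differed by -3.77, -3.67 and -2.88, Des, the muscle intermediate filament gene desmin, by -2.91, above background on 1 of the 2 maslinic acid arrays. Ddx51, an RNA helicase gene, was at least 4.26-fold lower, but among the 4 arrays compared only control array 1 lay above background, and it differed by -1.03 without that array. Fhl1, Aldoa, Neb and Mylpf differed by -5.20, -5.25, -4.89 and -5.75 without control array 1. Of the 31 muscle markers 29 were lower, 13 at the study's thresholds (median -1.40, camera adjusted p = 2.47e-09, and adjusted p = 0.749 with an estimated correlation). Adjusted over the list alone 8 passed, and none did over all genes. The median was -2.71 without control array 1, -0.61 without control array 2, where the call ended (adjusted p = 0.309), and -0.82 without maslinic acid array 2 (adjusted p = 4.55e-05, with 5.56e-23 to 0.831 over the alternatives).

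The named genes with the highest values under maslinic acid were led by Zfp966 and Zfp979, 11.8- and 10.2-fold higher and 1.92- and 1.56-fold higher without control array 1. Zfp970 went from 8.99- to 2.17-fold, Olfr994 from 9.26- to 4.17-fold, Vmn2r84 from 8.27- to 3.31-fold, and Vmn1r67 from 7.31- to 3.04-fold. The chromatin remodeller gene Smarca5 went from 7.36- to 1.92-fold, and Defa40 and the cullin gene Cul5 were at least 2.98- and 1.69-fold higher. Olfr994, Vmn2r84 and Vmn1r67 were above background on 1 of the 2 control arrays. With all 8 arrays, 13.5% of the 1429 receptor probe sets met the study's thresholds, 162 higher and 31 lower, against 10.7% of others. Without control array 1 the share of receptors was nearer to that of others but stayed above it. Defb46, a beta-defensin gene, was 7.48-fold higher (log2 2.90, SE 0.44) and 5.46-fold higher without control array 1, with an adjusted p of 0.0932 there by limma (0.000169 to 0.89 over the alternatives).

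Of 50 keratin-associated proteins 39 were higher with maslinic acid (median 0.74, camera adjusted p = 0.00393, and adjusted p = 0.749 with an estimated correlation), among them Krtap6-1, Krtap5-1 and Krtap21-1 at 2.11, 1.99 and 1.88 (0.37, 0.18 and 0.40 without control array 1), and 0 passed when adjusted over the list alone. The call ended without control array 1, where the median turned to -0.05 (adjusted p = 0.906, with 2.52e-05 to 0.906 over the alternatives), and without control array 2 it was 1.32. Krt40, a hair keratin gene, was higher by 1.72 (SE 0.39) and was the 1 of 12 hair shaft keratins that passed when adjusted over the list alone, beside Krt39 at 1.24. Interferon-stimulated genes were lower for 19 of 25 members (median -0.41, camera adjusted p = 0.0191, and adjusted p = 0.749 with an estimated correlation), Ddx58 and the GTPase gene Gbp3 at least 1.64- and 1.80-fold lower but above background on control array 1 alone, and Irf7 below background in both groups, and 0 passed over the list alone. That call ended without control array 1 (-0.06, adjusted p = 0.989), without maslinic acid array 1 (-0.27, adjusted p = 0.0881) and among brighter probe sets (adjusted p = 0.0586, with 0.00249 to 0.992 over the alternatives), and the median was -0.68 without control array 2. The inner root sheath held Krt71 at -1.55 (-4.02 without control array 1 and 0.92 without control array 2), Krt27 at -1.17 (0.12 without control array 1) and Tchh at 1.12 and was not called (adjusted p = 0.692). Its median of 0.04 and mean of -0.13 differed in sign. Bulge and hair germ markers, with Sox9, a transcription factor gene of hair stem cells, at 1.64 and Aspn at 1.03 (0.90 and 0.24 without control array 1), and cornified envelope genes, with the protease genes Klk7 at 1.96 and Asprv1 at 1.87 (1.37 and 0.43 without it), were not called either (adjusted p = 0.465 and 0.58). Krtap21-1, Krt39, Sox9, Aspn, Klk7, Asprv1, Ccn2 and Fgf22 were above background on 1 of the 2 control arrays. No member of the growth factor list passed when adjusted over it alone, with Ccn2 at 1.81, Bmp6 at -1.41 and Fgf22 at 1.33 (1.09, -0.92 and 0.16 without control array 1), and among the 6 minoxidil target genes Abcc8 at -0.72 (-0.39 without control array 1) and Sult1a1 at -0.54 lay below the study's thresholds. Medians of these 2 lists, -0.12 and 0.06, differed in sign from their means of 0.02 and -0.04, and the test direction was lower for both.

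Limma called 0 probe sets at an adjusted p under 0.05 for maslinic acid with all 8 arrays (smallest adjusted p 0.448), the ordinary linear model called 0, and 2409 had an unadjusted p of at most 0.05. The same 2409 met the study's thresholds, 1420 higher and 989 lower, against a mean of 3199 in simulated unchanged groups. Leaving out control array 1 gave 2840 (1380 higher, 1460 lower; 1190 shared) and the 1 adjusted call was Aldoa (log2 -5.25, adjusted p = 0.0441, with 0.0143 to 0.89 over the alternatives), named after its value was seen. Without maslinic acid array 1 the adjusted call was Myh4 alone (log2 -7.85, adjusted p = 0.022, with 0.0126 to 0.89 over the alternatives), and without control array 2 limma called 8282. At the study's thresholds the count was 10499 without control array 2, 1034 and 773 without maslinic acid array 1 or 2, and 1545 without either tieghemelin array. Groups did not overlap for 38.7% of probe sets against 33.3% by chance for arrays that vary alike. Here too the wider spread of the control arrays raises that chance share, so no excess is shown.

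**Figure D3:**
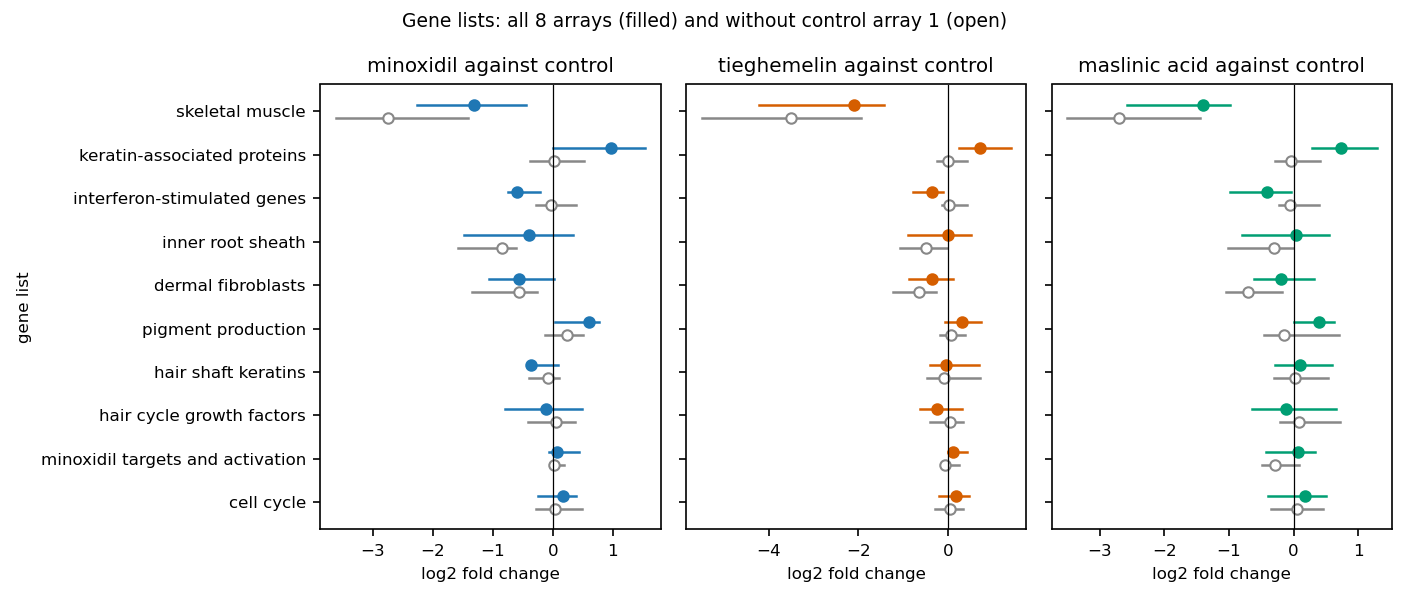
Median log2 fold change against control (points) and quartiles over members (lines) of 10 gene lists, with all 8 arrays (filled) and without control array 1 (open). The skeletal muscle median was -1.31, -2.09 and -1.40 with all arrays and lay farther from 0 without control array 1, whereas the medians of keratin-associated proteins moved to near 0.

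Tieghemelin and maslinic acid were applied at the same dose for the same time. Skeletal muscle markers were lower with tieghemelin than with maslinic acid for 28 of 31 members, with a median of -0.78 (camera adjusted p = 4.57e-14, and adjusted p = 0.77 with an estimated correlation). Tnnt3, above background on 1 of the 2 tieghemelin arrays, differed by -4.04 (95% interval -6.70 to -1.39), Myh8, Myh1, Ttn and Atp2a1 by -2.48, -2.37, -2.17 and -1.72, and Myl1 by -2.48 (-7.50 to 2.55). The interval for Mylpf, -6.84 to 1.85, included 0, and Acta1, for skeletal actin, differed by between -3.76 and -0.24. The muscle call ended without maslinic acid array 1 (median -0.17, adjusted p = 0.359, with 5.66e-31 to 0.77 over the alternatives), where Mylpf turned to 0.86, and the median was -1.46 without maslinic acid array 2. Bulge and hair germ markers were lower for 11 of 12 members (median -0.21, camera adjusted p = 0.0135, and adjusted p = 0.77 with an estimated correlation), with Sox9 at -0.87 (-2.04 to 0.295) and Aspn at -0.71. The interval of Sox9 excluded 0 without control array 1 (-1.53 to -0.216). That call ended without maslinic acid array 1 (-0.16, adjusted p = 0.359), without tieghemelin array 2 (-0.19, adjusted p = 0.391) and among brighter probe sets (adjusted p = 0.128, with 0.00844 to 0.77 over the alternatives), and the median was -0.33 without maslinic acid array 2. For both lists 0 members passed over all genes and 0 when adjusted over the list alone.

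Other genes that were higher with tieghemelin than with maslinic acid included the macrophage gene Aif1 at 1.25 (95% interval 0.0593 to 2.45) and S100a9 at 1.18. The potassium channel gene Kcns2, Igfals, which binds insulin-like growth factors in blood, and Serpinb9d lay below background on both maslinic acid arrays and were at least 1.59-, 1.67- and 1.47-fold higher. Ssxb3, Zfp273, Vmn1r123, AW112010 and Tmed3 lay between 1.07 and 1.22, and Aif1 and AW112010 were above background on 1 of the 2 maslinic acid arrays. Lower values were found for the calcineurin gene Ppp3cb at -1.68, Tpm2 at -1.63 and Parp6 at -1.21, and Olfr391 was at least 1.96-fold lower. The wound-response gene S100a8 differed by 1.15, the hair keratin Krt35 by -0.77, the growth factor genes Igfbp3 and Angpt1 by -0.78 and -0.62, the fat gene Fabp4 by -2.18, and the minoxidil target genes Abcc8 and Sult1a1 by 0.72 and 0.46, each with a 95% interval that included 0 with all 8 arrays. Lcn2 and Ucp1, below background on both maslinic acid arrays, were at least 1.2- and 1.37-fold higher. Their measured intervals and that of Krt32, a hair keratin gene below background on both tieghemelin arrays, also included 0. Lcn2 and Krt35 were above background on 1 of the 2 tieghemelin arrays. When control array 1 was left out, the intervals of Lcn2 (0.126 to 1.75), Krt32 (-1.46 to -0.134), Krt35 (-1.44 to -0.0924) and Fabp4 (-4.21 to -0.149) excluded 0. Without tieghemelin array 2, S100a8 turned to -0.25.

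Limma called 0 probe sets between tieghemelin and maslinic acid (smallest adjusted p 1), the ordinary linear model called 0, and 68 had an unadjusted p of at most 0.05 and met the study's thresholds, 31 higher and 37 lower, against a mean of 127 in simulated unchanged groups. The group means correlated at r = 0.98 across genes, which are not independent replicates. The 95% interval of the difference reached a median of 1.07 log2 units to either side. Similar values would not by themselves show similar action. Only 12.3% of probe sets had an interval within 2-fold, so similar values were not shown for the rest. Without control array 1, whose spread enters the shared error, that share was 59.4% and the count at the study's thresholds 347, as it was without control array 2. The count was 32 and 33 without tieghemelin array 1 or 2 and 27 without maslinic acid array 1. Groups did not overlap for 30.6% of probe sets, below the 33.3% of chance.

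**Figure D4:**
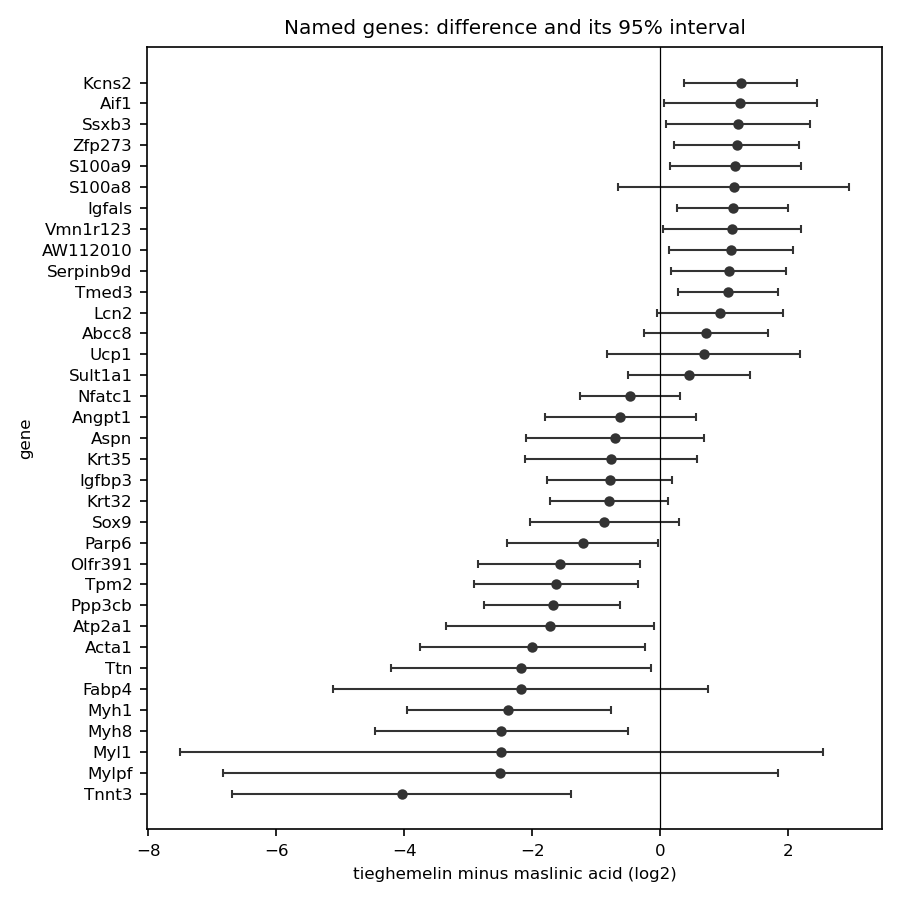
Difference of tieghemelin minus maslinic acid (points, log2) with its 95% interval from limma on all 8 arrays (bars, n = 2 arrays per group) for the named genes of this comparison. Tnnt3 lay lowest at -4.04 and Kcns2 highest at 1.26, as measured, including genes that lay below background in 1 or both groups.

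Against minoxidil, Tchh, the gene of the inner root sheath protein trichohyalin, was higher with both tieghemelin (log2 2.23, SE 0.45) and maslinic acid (2.35, SE 0.45). Foxr2 was likewise among the named genes of both, at 2.23 with tieghemelin and 1.93 with maslinic acid, as was Prxl2b, at least 4.01- and 3.15-fold higher. S100a8 was at least 2.48-fold higher with tieghemelin and Aox3, an aldehyde oxidase gene, higher by 2.16, and Esf1, a ribosome assembly gene, and Dpy30, a histone methylation gene, with maslinic acid by 2.05 and 1.98. Muscle genes were lower with tieghemelin than with minoxidil, with Mylpf 31.9-fold lower, Car3 and Tnnt3 at -3.81 and -3.16 and Neb at least 4.15-fold lower, and the muscle list, tested here after the data were seen, had 26 of 31 members lower (median -0.98, camera adjusted p = 1.2e-06, and adjusted p = 0.916 with an estimated correlation). With maslinic acid the lowest values relative to minoxidil were those of Apol7d at -2.41, Sorbs2, an adaptor gene of muscle, at -2.22, Olfr133 at -1.95, Olfr1138 at -1.82 and Ascl3, a transcription factor gene, at -1.76. Apol7d and Sorbs2 were above background on 1 of the 2 maslinic acid arrays, Dpy30 on 1 of the 2 minoxidil arrays and Tnnt3 on 1 of the 2 tieghemelin arrays. Limma called 0 probe sets for either compound against minoxidil (smallest adjusted p 1 for both), as did the ordinary linear model, with 732 and 800 at an unadjusted p of at most 0.05 and at the study's thresholds, against 126.4 and 128 in simulated unchanged groups. Those counts were 2314 and 2463 without control array 1, and the same without control array 2. Groups did not overlap for 43.8% and 43.6% of probe sets against 33.3% by chance.

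The log2 fold changes of the 3 treatments, computed against the same control arrays, correlated across genes at r = 0.826 for minoxidil and tieghemelin, 0.814 for minoxidil and maslinic acid and 0.928 for tieghemelin and maslinic acid. Simulated unchanged groups that shared simulated controls gave r = 0.906. The covariances were 0.602, 0.571 and 0.659 against a simulated 0.567, differences of 0.0348, 0.00392 and 0.0917. At the study's thresholds 653, 580 and 973 higher probe sets were shared, where independent lists would share 109, 99.1 and 99.6, and 439, 419 and 612 lower ones, where independent lists would share 45.1, 42.4 and 46.8. Simulated unchanged groups with shared controls of a modelled spread had a mean of 1100, 1099 and 1099 higher and 1100, 1100 and 1098 lower probe sets in common, more than were observed. The 2 control arrays could not be split with 2 in each part, so part or all of the excess over independent lists may come from the shared controls. Muscle genes such as Tnnt3, Myh4, Myh8, Fhl1, Aldoa and Neb were among the named lower genes of all 3 treatments, and Olfr994 and Vmn2r84 among the named higher genes.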

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

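The tests of both patterns in this part were chosen only after the result was seen. The dap control probe set, outside the measurement of mouse genes, read 8.518 on tieghemelin array 2 and 8.309 on maslinic acid array 1, above the highest control array at 7.049.

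Control array 1 stood apart from the other 7 arrays. Its 4 hybridization spikes lay at least 3.81 log2 units below the lowest other array, which argues against another sample under this label that was otherwise processed alike, since spikes are added to each sample alike. A missing spike mix alone is argued against by the mouse genes, which correlated with those of other arrays at no more than 0.538, where the other 7 arrays correlated at 0.901 or more. A failed hybridization stays open, since the low spikes prompted its test, and so does an equal loss of signal for all transcripts: the skeletal muscle median lay -1.58 log2 units from control array 2, outside the central 95% range of -3.69 to -1.92 of 10000 random lists of like brightness by 0.335, which is less than the 1.35 between the 2 maslinic acid arrays. The design gives no biological difference between the control arrays, so no biological explanation was tested.

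Skeletal muscle genes were lower in most treated arrays than in the control arrays. Control array 1 alone is argued against as the cause, because leaving it out moved the list's median away from 0, to at least 1.67 times its value in each treatment. Leaving out control array 2 moved the median towards 0, to -0.70, -1.36 and -0.61 with minoxidil, tieghemelin and maslinic acid. That array had the highest muscle median, 12.06 against 10.40 on control array 1, so a part played by control array 2 stays open. Uneven amounts of muscle in the skin samples, which normally hold a thin muscle layer, may contribute: the arrays of maslinic acid differed by a median of 1.35 over the list, with 27 of 31 genes on the same side, while those of minoxidil and tieghemelin differed by 0.42 and 0.109. An effect of the treatments cannot be told apart from this with 2 arrays per group. The list's mean on the lowest control array, array 1, lay at -0.019 relative to the highest treated array, maslinic acid array 1. That gap near 0 rests on the array that stood apart: control array 2 had a mean of 12.49 against 10.70 on maslinic acid array 1. By rank within each array, the list's median percentile was 96.4 and 97.3 on the control arrays and at most 93.3 on a treated array.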

How the results depend on the processing

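The crossed block and the estimated correlation without control array 1 were chosen only after the results were seen. Counts at the study's thresholds for minoxidil, tieghemelin and maslinic acid against control, and tieghemelin against maslinic acid, were 2502, 2609, 2409 and 68. They were 1265, 1346, 1219 and 23 among brighter probe sets (fewer probe sets tested), 1203, 1365, 1193 and 408 with array weights, and 683, 964, 821 and 363 with only the arrays compared. The array weights were equal within each group, 0.219 for both control arrays, so they did not set control array 1 apart from control array 2. Without moderation the counts against control were 1467, 1570 and 1473. Leaving out 1 array gave 1189 to 10508, 815 to 10549, 773 to 10499 and 27 to 347, and adjusted counts against control of 0 to 8363, 0 to 8427 and 0 to 8282. Lists called numbered 0 in all 4 comparisons with an estimated correlation and 0 against control when control array 1 was also left out. They ranged, with 1 array left out, from 1 to 3 for tieghemelin, 1 to 3 for maslinic acid and 0 to 3 between those compounds, where 1 was called among brighter probe sets. The mean correlation of fold changes was 0.856 and ranged from 0.755 to 0.952. The left-out arrays that turned a direction were as follows, with the other end of the range in brackets. Without control array 2 the medians turned to 0.171 [-0.842] for the inner root sheath with minoxidil and 0.427 [-0.899] and 0.204 [-0.653] for dermal fibroblasts with minoxidil and tieghemelin. Krt71 turned to 0.739 [-4.201], 0.6665 [-4.274] and 0.9159 [-4.024] with minoxidil, tieghemelin and maslinic acid, Dcn and Krt5 to 0.6475 [-2.742] and 0.82 [-2.813] with minoxidil, and Col3a1 to 0.2035 [-2.608] with tieghemelin. Leaving out control array 1 turned keratin-associated proteins to -0.0478 [1.32] and Krt27 to 0.1199 [-2.458] with maslinic acid, Mfap5 to 0.02332 [-3.274] with minoxidil, and Kcnj8 and Hlf to -0.05148 [1.032] and 0.1647 [-3.498] with tieghemelin. Between tieghemelin and maslinic acid, Mylpf turned to 0.8645 [-5.858] without maslinic acid array 1 and S100a8 to -0.2488 [2.545] without tieghemelin array 2. Of the other values of genes and lists under alternatives, 3389 kept direction and side of the threshold, 157 passed it newly and 32, all of lists, no longer passed; the cause was not tested. Replicates share only a number: deviations of same-numbered arrays correlated at -0.17 to 0.0902, the replicate block gave 0 adjusted calls and 2450, 2565, 2316 and 51 at the study's thresholds, and the crossed block gave 0 adjusted calls between tieghemelin and maslinic acid. Across probe sets, tieghemelin array 1 correlated with maslinic acid array 2 at 0.966, above the pairs within tieghemelin (0.960) and maslinic acid (0.951). Tieghemelin array 2 and maslinic acid array 1 correlated at 0.959. Positive control probe sets were not separated from negative ones on any array, which limits all arrays and weak probe sets in particular. Positive exceeded negative ones with a probability (AUC) of 0.454 to 0.501 per array, where 0.5 is no separation. Control array 1, at 0.489, lay within that range.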

Other observations

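Of the tests in this part, the position of control array 2 and the receptor share with all 8 arrays were chosen only after the result was seen. In the lists not yet described, single genes stood out. Ms4a7, a macrophage gene, was 4.35-fold higher with minoxidil, 3.38-fold with tieghemelin and 4.3-fold with maslinic acid (SE 0.409 on the log2 scale, n = 2 arrays per group), and was in each the 1 of 14 macrophage markers that passed when adjusted over the list alone, where 0 passed over all genes. The scavenger receptor gene Mrc1 differed by 2.04 with tieghemelin and 1.63 with maslinic acid, and by 0.75 and 0.34 without control array 1, and the efferocytosis receptor gene Mertk was at least 1.16-fold higher with minoxidil. Here too a gene with no array of a group above background is given as at least so many fold. The macrophage list was not called (adjusted p = 0.473, 0.334 and 0.58 by limma's camera). Des was the 1 of 11 smooth muscle and pericyte markers that passed over the list alone in each treatment, at -2.35, -3.11 and -2.91, beside the contractile gene Tagln at least 1.30-, 1.75- and 1.71-fold lower but above background on control array 1 alone. Des was above background on 1 of the 2 maslinic acid arrays. Skeletal muscle also expresses Des, and the list was not called (adjusted p = 0.388, 0.413 and 0.465). Its median under maslinic acid was 0.22 while its mean was -0.41.

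Sebaceous gland markers were lower for 11 of 18 members in each treatment without a call (adjusted p = 0.388, 0.55 and 0.465). Far1, which makes fatty alcohols, was at least 1.54-, 2.07- and 2.03-fold lower, and Cidea, a lipid droplet gene, at least 1.60-fold lower with minoxidil, but each was above background on control array 1 alone. Pm20d1 lay below background with tieghemelin, with maslinic acid and in control skin. In the basal epidermis, Itga6, a basal cell integrin gene, was at least 2.62-fold higher with minoxidil and 2.61-fold with maslinic acid, Trp63, a basal cell transcription factor gene, differed by -1.42, -1.51 and -1.31, and Krt5, a basal keratin gene, by -2.39 with tieghemelin (-4.20 without control array 1). With minoxidil Krt5 differed by -2.81 without control array 1 and by 0.82 without control array 2. Among 17 clock genes, Nr1d2 differed by 1.70 with minoxidil and Bhlhe40 by -1.51 with tieghemelin (0.81 and -0.37 without control array 1). Nr1d2 and Hlf were above background on 1 of the 2 control arrays, and Hlf on no minoxidil or tieghemelin array. With maslinic acid Per1, at least 1.13-fold higher, was the 1 that passed over the list alone, and Tef, above background on control array 1 alone, was at least 1.70-fold lower. The 36 cell cycle genes had medians of 0.17, 0.17 and 0.18 without a call (adjusted p = 0.862, 0.767 and 0.771).

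Minoxidil arrays differed from those of tieghemelin and maslinic acid at 732 and 800 probe sets by the study's thresholds, against 68 between those compounds, and at 2314 and 2463 against 347 without control array 1. That an array-wide technical difference could account for this was tested by the share of 1429 receptor probe sets (odorant, vomeronasal and trace-amine) at an unadjusted p of at most 0.05 in both comparisons, with bounds of 10% or more for it and 5% or less against it set beforehand. In the fit without control array 1, where the pattern was first seen, the share was 8.26% (95% interval 6.88 to 9.81, exact binomial), between the bounds, against 7.24% of other probe sets and 1.03% in 20 draws of unchanged groups. With all 8 arrays it was 1.89% (1.25 to 2.74) against 1.64% of other probe sets and 0.0723% in 20 such draws, which is below 5% but excludes nothing, because the other probe sets lay below 5% as well, a reason found after the values were seen. That test did not use direction. At the study's thresholds with all 8 arrays, 12 receptors were higher and 33 lower with tieghemelin than with minoxidil, and 10 and 52 with maslinic acid. Among all probe sets 392 were higher and 340 lower with tieghemelin, and 433 and 367 with maslinic acid. Background medians, 7.33 and 7.51 with minoxidil and 6.96 to 7.08 with the other compounds, also differed between these arrays, and their part was not tested. A change in the minoxidil arrays alone was tested by the place of control array 2 between the minoxidil mean and the mean of the other compounds. Its title calls that array the control of tieghemelin and maslinic acid, so it may not be a neutral reference. Over 1285 genes picked without controls its median place was 0.501, midway, and both explanations stay open.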
